A study of Mus musculus with 11 samples.

How the data were processed

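The samples were 11 ChIP-seq libraries of MEL cells, 1 per group. According to the labels they were HA, IgG, H3K27ac, H3K4me1 and input in cells with NFIA-ETO2, HA and input in control cells, and H3K27me3, H3K9me1 and their 2 inputs, whose titles name control cells and whose genotype labels name the fusion. By its title, the input of H3K27me3 is also that of H3K4me1. Peak lists of 7 libraries were analysed and the 4 inputs were not analysed here on their own. Cells were fixed with formaldehyde and libraries were sequenced on an Illumina instrument, per the labels' protocols. Reads were processed with Bowtie2, SAMtools 1.11, Picard and MACS2 2.2.7.1 on the mm10 build, per the submitters' processing notes. The settings of these steps were not used here.

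Each list holds 1 library and 1 row per peak. The authors' peak caller gave a fold enrichment ratio per peak, a −log10 p-value and a −log10 q-value, and a score derived from the last, per the deposited columns. HA, IgG and H3K27ac came as narrow peaks with a summit, and H3K4me1, H3K27me3 and H3K9me1 as broad peaks, where the fold and −log10 values deposited are means over the region. The names of the deposited lists give an FDR of 0.05. The values show other limits in some lists: the largest q was 0.00977 in the fusion HA list and 0.0987 to 0.0997 in the broad lists. It was 0.0495 in the H3K27ac list, 0.0359 in the control HA list and 0.00463 in the IgG list, all within 0.05. Scores, folds and q-values were used only within a list, to describe, rank or filter the authors' peaks.

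Depth is not given as read totals. In the narrow lists it was recovered in part, since the peak caller's fold is (reads + 1) / (background + 1) and its p-value is a Poisson tail of the same 2 numbers. Solving both gave whole reads at each summit and the local background, with a relative misfit of at most 2.6e-05 in −log10 p. On 2000 simulated peaks all backgrounds and read numbers were recovered within 1%. The simulated peaks did not reach the largest read numbers and backgrounds given below, nor the highest and lowest folds. For those values the misfit was the only check. The lowest background of a list, its floor, scales with library depth: 2.61 in fusion HA, 2.42 in control HA, 2.47 in IgG and 3.13 in H3K27ac. Above the floor, 74.2% of control HA, 68.2% of IgG and 48.7% of H3K27ac backgrounds were whole multiples (tolerance 0.01) of 1 step of 0.692, 0.604 and 0.768, as scaled reads of an input would give. In the fusion HA list at most 5.26% were, so that its backgrounds come from the library itself. The file name of that list also says that it was called without an input. Peaks in it at places where inputs hold excess reads were thus not held down as in the other lists. Since that background comes from the library itself, the reads of a peak count in its own background. Depth and background of the broad lists were not recovered.

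Peaks on chromosomes 1 to 19, X and Y were used. HA sites were fusion HA peaks that shared no base with a control HA or IgG peak. Overlap meant 1 bp or more. Gene positions came from the RefSeq annotation of GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on these chromosomes. It was used without strand, exons or transcripts. The planned windows around transcription start sites were therefore replaced by windows around both ends of each gene, which also count peaks at the 3′ end. A genome sequence was not used here, so the planned search for NFI, GATA and E-box motifs was not run. Of 239 list genes, 238 were found, 2 by an older symbol.

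The 15 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Nfia and Cbfa2t3, the 20 HA sites of highest fold by nearest gene, up to 4 members of each list with an HA site, and for each mark up to 3 members of each list by fold and the 5 highest or longest regions, of which examples are printed. A gene had an HA site if a summit lay inside it or within 10 kb. Shares have 95% Wilson intervals, which cover counting error only, and reads without molecular identifiers are not independent molecules. Expected shares came from 1000 random placements of the peaks, each on its own chromosome between the outermost peaks of any list. Expected lengths shared between marks came from 1000 shifts of all peaks of a chromosome by 1 random distance, or 200 for H3K9me1. Lists were compared with 10000 random lists matched on gene length in 10 groups, given as means and as the central 95% of lists. The H3K27ac folds of peaks with an HA site were compared with 1000 draws of peaks matched on width in 20 groups. Chosen after the data were seen were this comparison, 2 further matchings of lists, on length and highest H3K27ac fold, and on length and acetylated length within 10 kb, and a filter for low local background. It keeps HA sites with a background of at most 3 times the floor that overlap no H3K27ac peak with a background over 3 times its own floor. In the closing section excess reads at HA peaks were read from the H3K27ac list, whose background comes from an input, at H3K27ac summits within 1 kb of the HA summit. With 1 library per group no test between conditions was possible and no p-value was computed.

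Alternatives were a stricter q limit for HA or mark peaks, removal of HA peaks within 1 kb of a background peak or no removal, coverage of at least 50% of the HA peak, windows of 3 kb or of the gene end alone, H3K27ac peaks away from gene ends, the gene with the nearest end, and shares of peaks in place of length. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap counts were tested on simulated data, where all 200 peaks placed on targets among 1000 were found.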

Results

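The data covered chromatin immunoprecipitation with sequencing (ChIP-seq) in MEL cells, a mouse erythroleukemia line of red cell precursors arrested before terminal maturation. The cells were transduced with a viral vector for NFIA-ETO2. This fusion protein joins NFIA, a transcription factor of the nuclear factor I family, to ETO2 (gene Cbfa2t3), a co-repressor that works with the erythroid factors GATA1 and TAL1. The fusion carried an HA tag, a short peptide recognised by an antibody, so that HA ChIP marks where it bound. Peak lists were used for 7 of the 11 libraries: HA, IgG, H3K27ac and H3K4me1 ChIP in fusion cells, HA ChIP in control cells, and H3K27me3 and H3K9me1 ChIP. For these last 2 marks the titles name control cells and the genotype labels name fusion cells, so their genotype was left open. The other 4 libraries were inputs and have no peak list of their own here. Each group held 1 library, so no value below has a replicate error. Intervals are 95% Wilson intervals and cover counting error over peaks or genes only. Fold values are the authors' own enrichment per peak.

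The question asked of the HA libraries was where the fusion sits on the genome. On chromosomes 1 to 19, X and Y, HA ChIP gave 1293 peaks in fusion cells and 256 in control cells, and IgG ChIP in fusion cells gave 106. Of the fusion HA peaks, 17.5% (226 peaks, interval 15.5 to 19.6%) overlapped a control HA peak and 6.81% (88 peaks, interval 5.56 to 8.31%) overlapped an IgG peak. Random placement of the same peaks gave means of 0.00557% and 0.00255%. In the other direction, 88.3% of control HA peaks (interval 83.8 to 91.7%) and 83% of IgG peaks (interval 74.7 to 89.0%) lay under a fusion HA peak. Removal of these 238 peaks left 1055, called HA sites here. The fusion HA list was called without an input, while the control HA and IgG backgrounds came from one. Places with excess reads in inputs could thus stay as HA sites while held down in the other lists. The peak counts are therefore not like for like. The lowest background level recovered from the values, which scales with depth, was 2.61 reads in the fusion HA library, 2.42 in the control HA library and 2.47 in the IgG library. At shared peaks, reads at the summit scaled by this level were a median of 1.29 times those of control HA ChIP and 0.927 times those of IgG ChIP. At this level the smallest peak called held 15 reads in control HA ChIP and 16 in IgG ChIP. Of the 1055 HA sites, 433 and 411 had scaled reads of at least 2 times these limits. At the rest, a weaker signal in control HA or IgG ChIP could have gone uncalled. HA peaks were narrow, with a median width of 226 bp.

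Marks of active regulatory elements were each present at about 1 in 3 HA sites. H3K27ac, a mark of active enhancers and promoters, was present at 33.9% of HA sites (358 of 1055, interval 31.1 to 36.8%), against a mean of 2.64% for random placements. H3K4me1, a mark of active and primed enhancers, was present at 35.3% (372 sites, interval 32.4 to 38.2%), against 7.80% at random. H3K27me3, deposited by the Polycomb repressive complex, was present at 4.27% of HA sites (45 sites, interval 3.20 to 5.66%), below the random range of 5.97 to 9.19%. This deficit rested on the removal of shared peaks, since all fusion HA peaks gave 7.12%, within the random range of 6.11 to 9.05%. H3K9me1 was present at 17.6% (186 sites, interval 15.4 to 20%), against 11.3% at random. Both H3K27ac and H3K4me1 marked 259 sites, while 457 sites, or 43.3% (interval 40.4 to 46.3%), carried none of the 4 marks. Control HA peaks also lay in H3K27ac more often than at random, at 26.6% (interval 21.5 to 32.3%), an interval that overlaps that of HA sites. They lay in H3K4me1 less often than HA sites, at 23.0% (interval 18.3 to 28.6%), and in H3K27me3 more often, at 17.6% (interval 13.4 to 22.7%). IgG peaks were in H3K27ac at 12.3% (interval 7.31 to 19.9%).

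**Figure D1:**
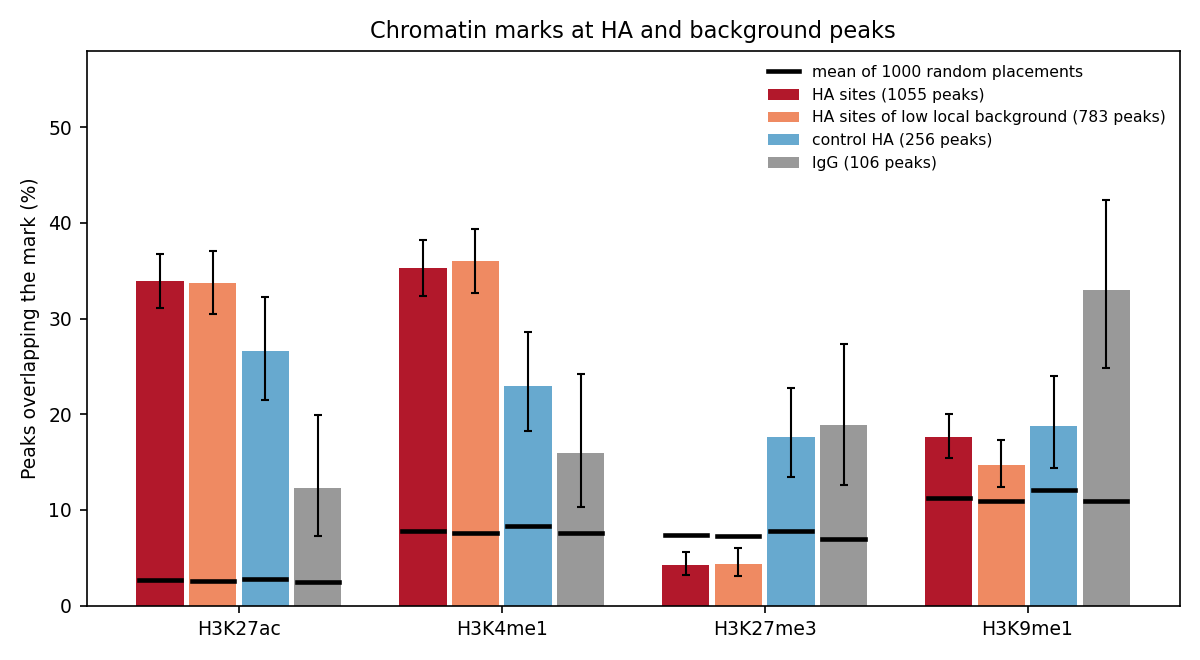
Share of peaks (%, vertical axis) that overlap each of 4 histone marks, for HA sites, HA sites of low local background, control HA peaks and IgG peaks. Whiskers are 95% Wilson intervals and black lines the mean of 1000 random placements: HA sites are at 33.9% for H3K27ac against 2.64% at random, and below the random mean only for H3K27me3.

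Most HA sites were away from gene ends. The gene annotation used gives the 2 ends of each gene but no strand, so a transcription start site could not be told from a gene's other end. The summits of 8.06% of HA sites (85, interval 6.56 to 9.86%) lay within 1 kb of either end of a protein-coding gene, against 3.02% at random. Of the summits, 36.3% lay inside a gene (interval 33.5 to 39.2%), within the random range of 36.1 to 41.9%. Whether a site was exonic or intronic was not analysed here. Among the 358 acetylated HA sites, 72.3% also carried H3K4me1 (interval 67.5 to 76.7%) and 16.5% lay within 1 kb of a gene end (interval 13.0 to 20.7%). Of the length of all H3K27ac peaks, 76.7% lay within H3K4me1, and counted by peaks the share was 87.9%. These measures of length and of whole peaks differ from a share of sites. The share at HA sites was no higher than either.

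Genes of the erythroid program had HA sites far more often than genes of the same length. Of the 76 genes on 4 erythroid lists fixed before the data were examined, 15 had an HA site inside the gene or within 10 kb of it, or 19.7% (interval 12.3 to 30.0%). Random lists of genes of like length held a mean of 2.2 such genes, and none of 10000 held more than 9. Of all protein-coding genes, 2.80% had an HA site. Acetylation was strong at these genes, and with random lists matched on gene length and acetylated length, a comparison chosen after the data were seen, the mean was 7.15 genes. The central 95% of these lists ran from 3 to 12, and 0.220% of them held as many as 15. Of the 15 sites, 13 lay in H3K27ac peaks and 9 in H3K4me1.

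In the list of erythroid transcription factors, 5 of 20 genes had an HA site, while Gata1, Lmo2, Ldb1 and Nfe2, named after their values were seen, had none. The 5 genes stood against a mean of 0.654 in random lists matched on length, of which 0.0600% held as many. Zfpm1, which encodes the GATA1 cofactor FOG1, had a site inside the gene at chromosome 8, 122309388 to 122309655 (mm10), with an HA fold of 9.67, in an H3K27ac peak of fold 145 and an H3K4me1 peak of fold 15.7. Klf1, an activator of globin and other erythroid genes, had a site 658 bp beyond the gene at chromosome 8, 84901252 to 84901417, with a fold of 6.49. Gfi1b, an erythroid repressor, had one 7117 bp outside the gene (chromosome 2, 28602239 to 28602417, fold 5.52), and Runx1 one inside the gene (chromosome 16, 92715683 to 92715848, fold 5.26). The fifth gene was Tal1, with a site inside the gene, 269 bp from its end (chromosome 4, 115056580 to 115056784), with a fold of 4.72, in an H3K27ac peak of fold 188. These 5 sites rested on 18 to 37 reads at the summit, over local backgrounds of 2.61 to 3.35 reads. With acetylated length also matched, the range of random lists for this list was 0 to 5, so that its count of 5 lay at the edge, and 8.3% of lists held as many.

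Red cell membrane and surface genes formed the list with most HA sites. Here 8 of 28 genes had 1, against a mean of 0.953 in random lists matched on length, none of which held as many. With acetylated length also matched, the mean was 2.21 and 0.1% of lists held as many. Gypc, which encodes glycophorin C, had a site inside the gene (chromosome 18, 32542392 to 32542754) with a fold of 15.2 and 65 reads. It lay at the edge of an H3K27ac peak of fold 59.9. Icam4, a red cell adhesion molecule, had a site at a gene end (chromosome 9, 21029314 to 21029568, fold 6.73). Slc4a1, which encodes the anion exchanger band 3, had a site inside the gene (chromosome 11, 102363693 to 102363912, fold 6.68) in H3K4me1 but outside H3K27ac. The highest fold on the list, 28.4 at Ank1 (chromosome 8, 23095396 to 23095800), came from a place where the background of the H3K27ac list was 104 times its floor. The remaining members with a site, Gypa, Epb42, Tmod1 and Xpo7, had folds of 5.45 to 6.33 and were named after their values were seen.

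Genes of haem synthesis and iron handling had HA sites at 2 of 20, within the random range of 0 to 2. They were Alas2, the enzyme of the first step of haem synthesis in red cells (chromosome X, 150549712 to 150549936, inside the gene, fold 6.27), and Abcb10, a mitochondrial transporter (chromosome 8, 123988749 to 123988939, outside the gene, fold 5.51). None of the 8 globin genes had an HA site, with an upper interval bound of 32.4%, and random lists gave 0 to 1.

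**Figure D2:**
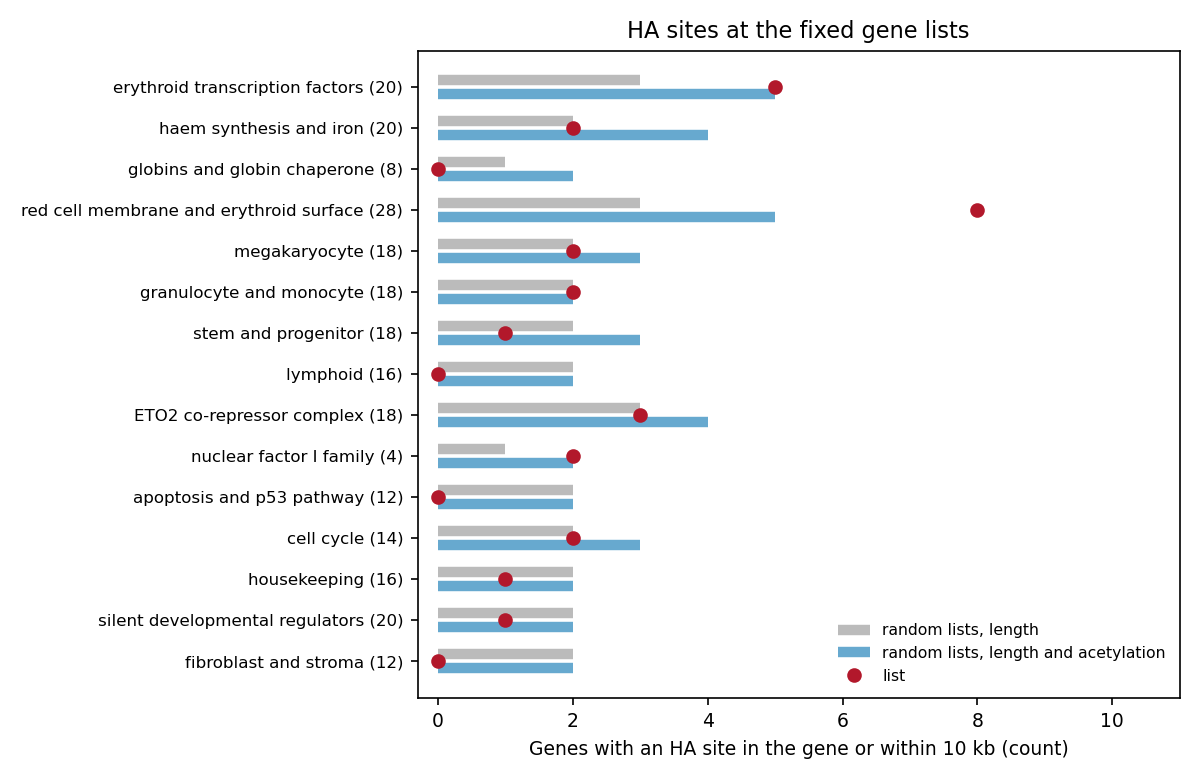
Number of genes with an HA site in the gene or within 10 kb (horizontal axis) for each of 15 gene lists (number of genes in brackets), as red points. Bars span the central 95% of 10000 random lists matched on gene length (grey) or on gene length and acetylated length (blue): red cell membrane genes, at 8, are the only list outside both bars.

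**Figure D3:**
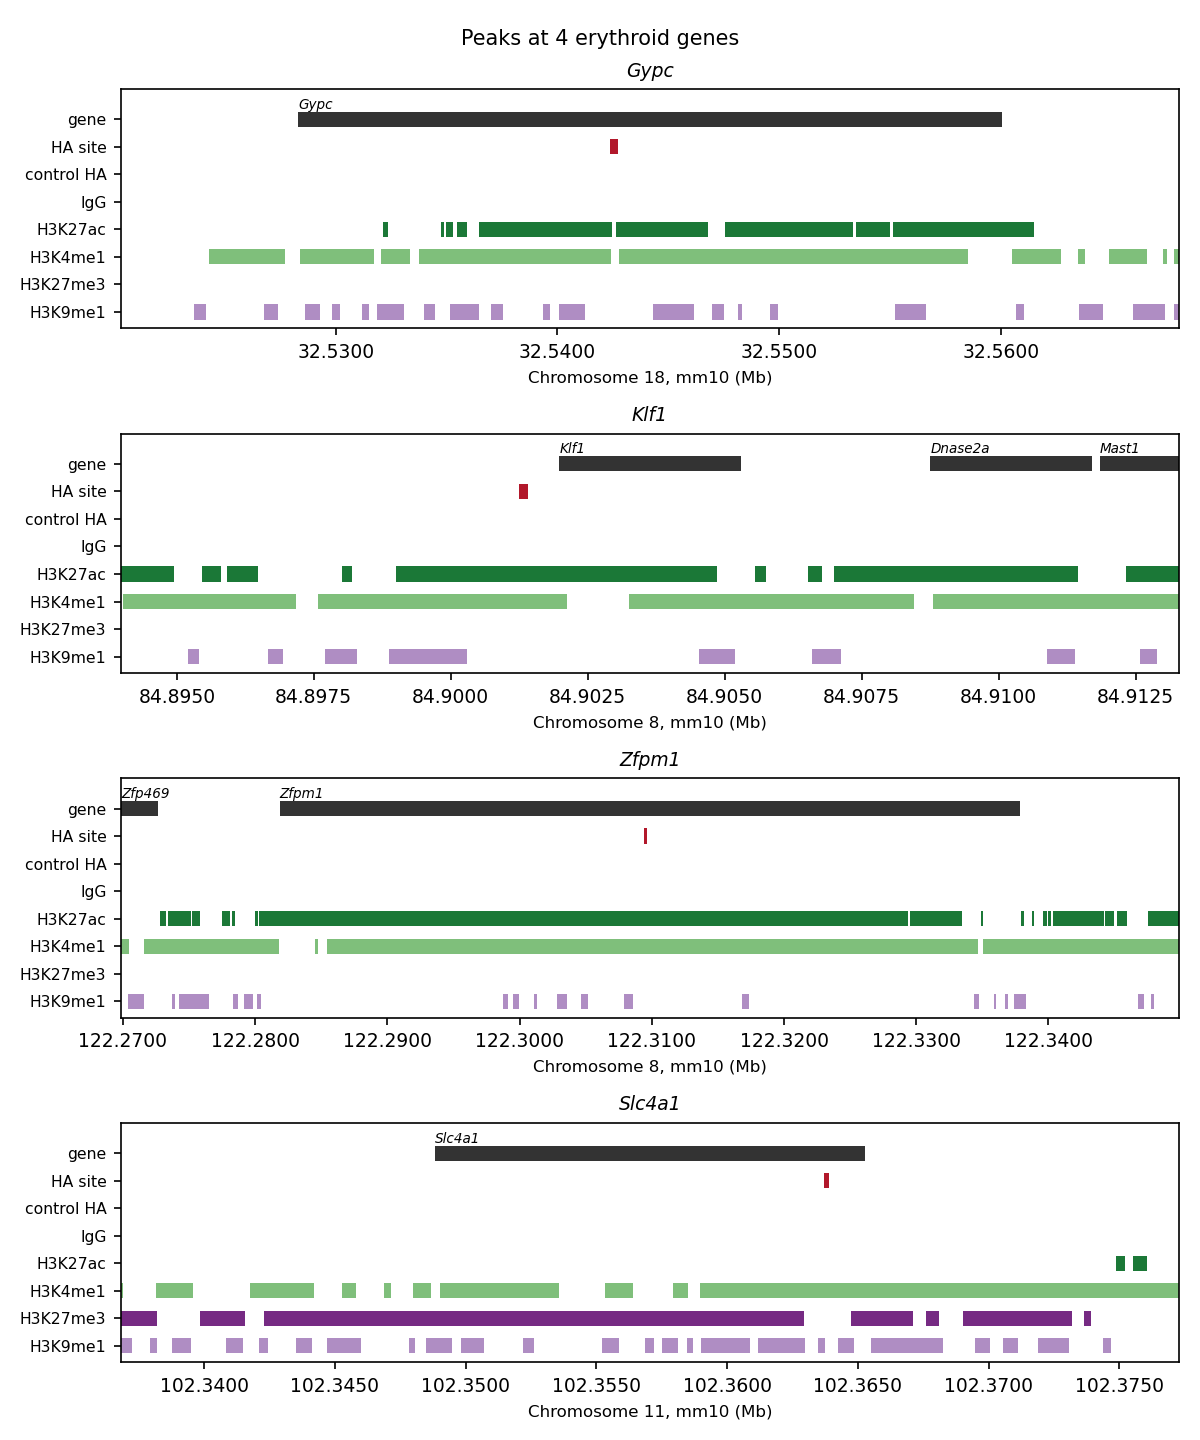
Positions (Mb, mm10, horizontal axis) of genes, HA sites, control HA, IgG and histone mark peaks at Gypc, Klf1, Zfpm1 and Slc4a1, 1 row per list. Each HA site is narrow and without a control HA or IgG peak nearby, and at Slc4a1 it lies between 2 H3K27me3 peaks.

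The genes of the fusion's own parts were examined in every list. Nfia, on chromosome 4 from 97578066 to 98118876, held 2 fusion HA peaks. One, at 97814887 to 97815159 with a fold of 12.2 and 48 reads, was an HA site in H3K4me1 (fold 5.85). The other, at 97783077 to 97783639 with a fold of 6.88 and 29 reads, was removed. It overlapped a control HA peak of fold 4.49 and 19 reads, and an IgG peak of fold 3.27 and 26 reads. The folds of these lists come from unlike backgrounds and do not compare signal. Cbfa2t3, on chromosome 8 from 122625136 to 122699332, held no HA peak inside the gene. An HA site lay 1589 bp outside it, at 122700831 to 122700998, with a fold of 4.97, in an H3K27ac peak of fold 85.9. Neither gene carried H3K27me3. In the nuclear factor I family 2 of 4 genes had an HA site, Nfia and Nfix, against 0 to 1 in random lists matched on length and 0 to 2 with acetylated length also matched. Nfix had 2 sites inside the gene, with folds of 6.75 and 4.29, both in an H3K27ac peak of fold 103. Of the ETO2 co-repressor complex list, 3 of 18 genes had a site: Cbfa2t3, Gfi1b and Tal1. Matched on length, 3.10% of random lists held as many, and 18.6% did with acetylated length also matched.

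The other lists lay within the range of random lists matched on length. Megakaryocyte genes had HA sites at 2 of 18, which were Plek (fold 4.51) and the thrombopoietin receptor gene Mpl (fold 3.88). The granulocyte and monocyte list had 2 of 18, the myeloid factor gene Spi1 (fold 4.62) and Fcgr3 (fold 4, over a background 3.35 times the floor). The cell cycle list had 2 of 14, E2f2 (fold 7.37) and Ccnd3 (fold 4.51). Single genes with a site were Pbx1 among 18 stem and progenitor genes (fold 4.76), Sox1 among 20 silent developmental regulators (fold 12.7, in none of the 4 marks) and Eef1a1 among 16 housekeeping genes. The 16 lymphoid, 12 apoptosis and p53 pathway, and 12 fibroblast and stroma genes had none, with upper interval bounds of 19.4%, 24.2% and 24.2%.

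The 20 HA sites of highest fold, from 28.6 to 64.0, had a median of 404 reads at the summit, against 28 for all HA sites. Of these, 5 lay in H3K27ac, 3 in H3K4me1 and 8 inside a gene. The first were near Dpy19l2 (chromosome 9, 24541959 to 24542241, fold 64.0), near Pak3 (chromosome X, 143482924 to 143483193, fold 63.9), in Chl1 (chromosome 6, 103649062 to 103649368, fold 63.1) and near Rab10 (chromosome 12, 3109796 to 3110133, fold 58.6). Their summits held 37533, 23170, 141479 and 343038 reads, over local backgrounds of 586, 362, 2240 and 5850 reads, which are 139 to 2240 times the floor. Sites in 2210408I21Rik and Cdk5rap2 and near Rpusd4 followed, with folds of 58.5, 57.1 and 43.1. In or near Mamdc2, Oasl1, Fam107a and Litaf the HA sites had folds of 32.2 to 41.5 and lay in weak H3K27ac peaks of fold 1.23 to 2.56. There the background of the H3K27ac list was 102 to 185 times its floor. The remaining 9, with folds of 28.6 to 39.6, were in or near Chl1 (another site), Tnc, Frmd4a, Cyp2b19, Cldn34d, Pcnx2, Eef1a1, Gm21425 and Fam171a1. The fusion HA background includes the reads of the peaks themselves, so it gives no independent measure of excess reads at these sites. The folds divide by that background, so a peak's own reads also hold its fold down.

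**Figure D4:**
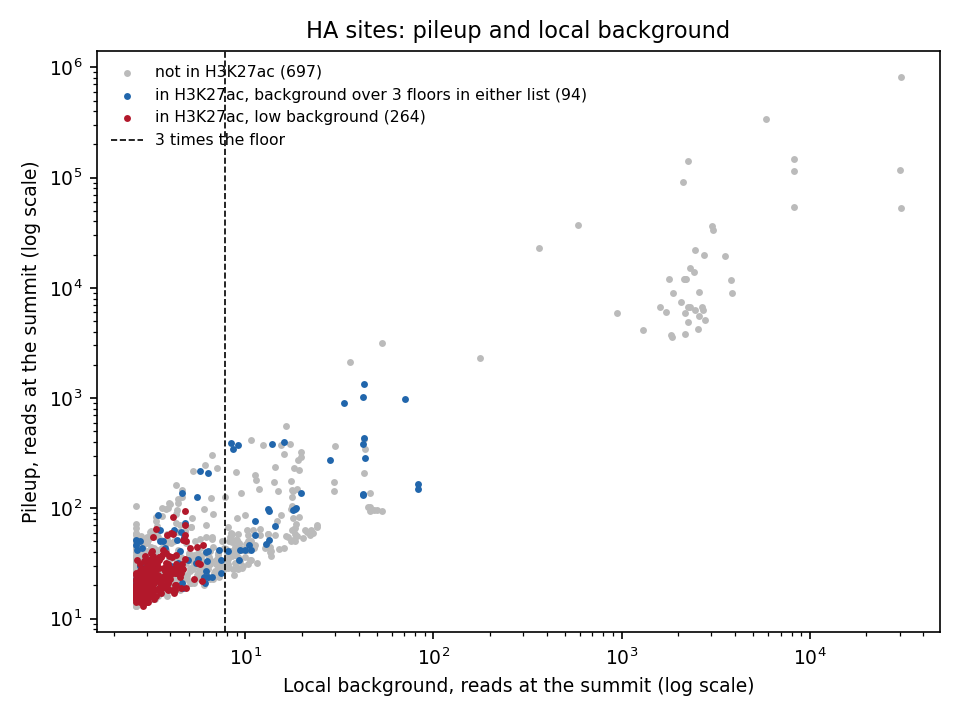
Reads at the summit (vertical axis, log scale) against local background (horizontal axis, log scale) of the 1055 HA sites, both recovered from the deposited values. The 264 acetylated sites of low background (red) lie at a median of 22 reads, while the sites right of the dashed line, at 3 times the floor, include the sites with most reads. The background counts a site's own reads, so many reads alone can move a site to the right of that line.

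Sites in acetylated chromatin with low local background included Sema4b, Def8, Gypc and Tmcc2, with the highest folds. These 264 sites, in H3K27ac and with a background of at most 3 times the floor in both lists, were picked out after the data were seen. Before the removal of shared peaks, fusion HA ChIP gave 295 peaks of this kind out of 1293, control HA ChIP 33 out of 256 and IgG 12 out of 106. Each library's own background was used, which came from an input in control HA and IgG but not in fusion HA. These counts are therefore not like for like. The HA background counts a site's own reads, so this filter can also drop acetylated sites with many reads. Eef1a1, with an HA fold of 30.7, was dropped for its HA background of 16.3 times the floor. The background of the H3K27ac list there was 1.23 times its floor. Of the 264 sites kept, the highest fold was in Sema4b (chromosome 7, 80208901 to 80209331, fold 16.6 over 95 reads, H3K27ac fold 106). Next came Def8 (8615 bp outside the gene, fold 16.3), Gypc (fold 15.2), Tmcc2 (fold 13.2), and Kmt2a, which encodes the histone methyltransferase MLL1 (fold 12.3, 366 bp from a gene end). Kmt2a was the nearest gene of 6 HA sites, of which 1 lay in H3K27ac. Cdkl1 followed (fold 12.1), then Slc6a9, the glycine transporter that supplies haem synthesis in red cells (chromosome 4, 117830098 to 117830384, 5007 bp outside the gene, fold 11.9, H3K4me1 fold 13.0). Zfpm1 ranked 11. Of these 264 sites, 78.8% carried H3K4me1 (interval 73.5 to 83.3%). For all H3K27ac peaks the share was 76.7% by length and 87.9% counted by peaks, measures unlike a share of sites. Within 1 kb of a gene end were 18.9% (interval 14.7 to 24.1%), and 48.1% were inside a gene (interval 42.1 to 54.1%), against 41.1% at random.

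H3K27ac peaks with an HA site were stronger than those without. The 383 H3K27ac peaks with an HA site had a median fold of 33.6, against 4.90 in the 57793 peaks without, a ratio of 6.85 (bootstrap interval 6.01 to 7.70). Their median widths were 2161 bp and 453 bp, and most of the ratio went with width. Random draws of peaks of like width without an HA site, a comparison chosen after the data were seen, had a mean median fold of 22.1 (range 19.1 to 25.6), which leaves a ratio of 1.52. Among H3K27ac peaks of low background, those of the top 10% by fold, from 33.1 upwards, had an HA site of low background at 3.21% (184 peaks), against 1.13% in the next 10% and 0.0349% in the lowest 10%. Control HA peaks marked 14 of these 5733 peaks, against 1 to 3 in each lower 10%, so they too were most frequent at the strongest H3K27ac peaks. IgG peaks marked 2. H3K27ac ChIP in control cells was not analysed here, so whether acetylation differed between fusion and control cells cannot be said.

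The chromatin of the gene lists followed cell identity. Within 1 kb of a gene end, H3K27ac was present at 49.4% of all protein-coding genes (interval 48.7 to 50%), and at 69 of the 76 erythroid genes, where random lists matched on length held a mean of 38.6. All 20 erythroid transcription factor genes and all 20 haem and iron genes had it, as did 22 of 28 membrane genes and 7 of 8 globin genes. Tal1 had the highest fold among the factors, at 188, before Zfpm1 (145) and Tcf3 (144). Epb41, which encodes the membrane skeleton protein 4.1R, reached 219, Cd47 167 and the carbonic anhydrase gene Car2 155. Abcb10 (115), Fech (102) and Uros (90.3) led the haem list. Among the globin genes, Hba-a2 (73.8), Hba-a1 (62.2) and the adult beta globin gene Hbb-bt (48.5) stood above the embryonic Hbb-y (12.7). Duplicated alpha globin genes share sequence, so reads may have been split between them.

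Genes of the cell cycle (13 of 14, led by Mki67 at 145), housekeeping (15 of 16, led by Actb and Ubc, both at 144), the ETO2 complex (17 of 18, led by Tal1 and Hdac2, at 133) and the p53 pathway (11 of 12, led by Gadd45a at 123) were also mostly acetylated. In the nuclear factor I family Nfix (139, in a peak that also covers Lyl1) and Nfic (28.7) had H3K27ac at a gene end, while Nfia and Nfib did not. Inside Nfia, away from its ends, were 48 H3K27ac peaks, the highest of fold 59.9. Lists of other lineages were not: 2 of 18 granulocyte and monocyte genes, 3 of 16 lymphoid genes, 3 of 20 developmental regulators and 0 of 12 fibroblast genes had H3K27ac at an end, below the random ranges of 5 to 13, 5 to 12, 6 to 15 and 3 to 10. The 2 acetylated granulocyte and monocyte genes were Spi1, with a fold of 68.1, and Prtn3, with 13.8. Megakaryocyte genes lay between, at 9 of 18 (random mean 8.71), with Gp9 at 109, Plek at 104 and Itga2b at 43.4. Stem and progenitor genes were acetylated at 6 of 18, with Gata2 at 76.2 and Bmi1 at 43.6. H3K4me1 was present at an end of 60.3% of all genes (interval 59.6 to 60.9%) and at 73 of the 76 erythroid genes (random mean 46.7), led by Steap3 (fold 11.6), Gypc, Lyl1 and Stat5a (each 10.9). Developmental regulators had it at 5 of 20, below the random range of 8 to 17, while granulocyte and monocyte (8 of 18), lymphoid (7 of 16) and fibroblast genes (5 of 12) lay within their random ranges.

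H3K27me3 gave the opposite picture. It was present at an end of 15.0% of all genes (interval 14.6 to 15.5%) and at 2 of the 76 erythroid genes, Slc4a1 and Add2, where random lists held a mean of 11.4. Of the fibroblast genes 7 of 12 had it, led by Pdgfra (fold 6.80), Col1a1 (5.90) and Col1a2 (4.66), of the developmental regulators 10 of 20, led by Hand1 (6.96) and Hoxd13 (4.74), of the granulocyte and monocyte genes 9 of 18, led by Itgam (5.91) and Csf1r (4.65), and of the lymphoid genes 8 of 16, led by Cd4 (4.47) and Gzmb (4.27). The means of their random lists were 1.87, 3.04, 2.66 and 2.53. Kit, the stem cell factor receptor gene, was among 4 of 18 stem and progenitor genes with it (fold 5.28), and Itgb3 (5.61) among 4 of 18 megakaryocyte genes. None of the ETO2 complex, p53, cell cycle or housekeeping genes had H3K27me3 at an end.

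**Figure D5:**
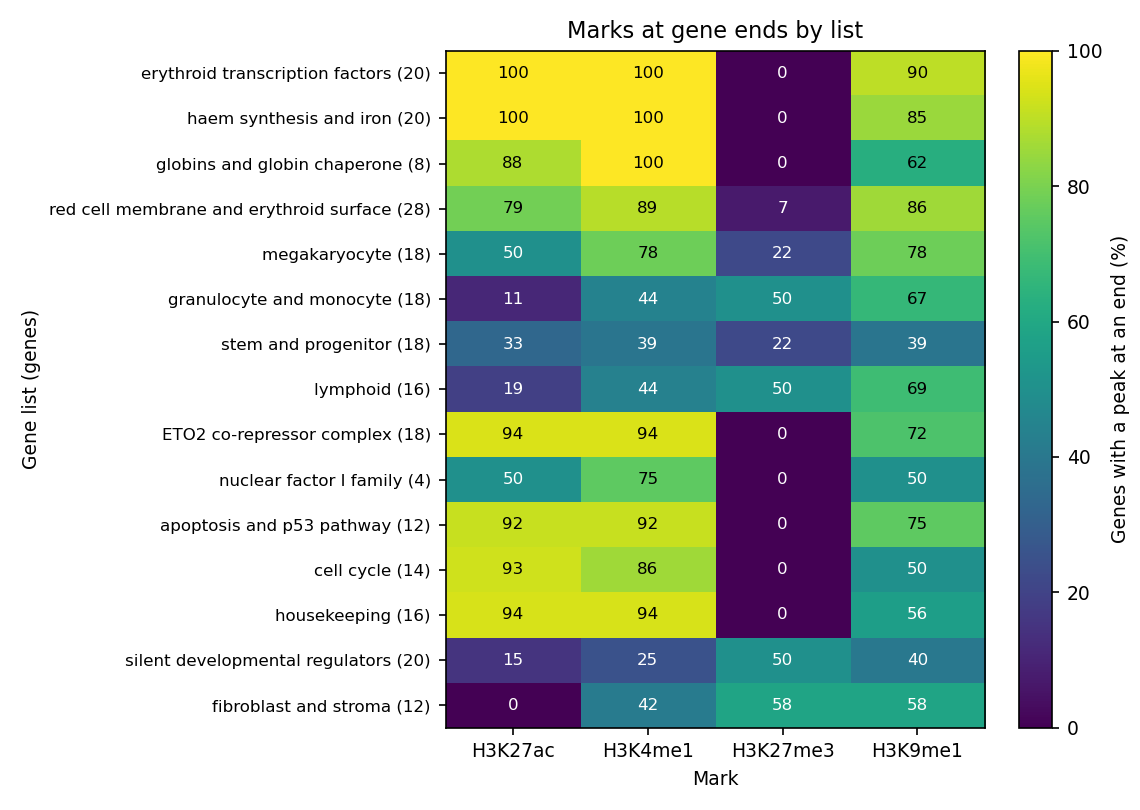
Share of each gene list (%, colour and printed value) with a peak of each mark within 1 kb of either gene end, with the number of genes in brackets. Erythroid, cell cycle and housekeeping lists are high in H3K27ac and H3K4me1 and near 0 in H3K27me3, while developmental, fibroblast, lymphoid and granulocyte lists have 50% or more of their genes in H3K27me3.

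H3K9me1, a mark found over transcribed and regulatory chromatin, was present at an end of 58.2% of genes (interval 57.6 to 58.9%), and at 64 of the 76 erythroid genes against a random mean of 44.8. Urod (fold 3.77), Abcb7 (3.60), Steap3 (3.56) and Stat5a (3.53) led the erythroid genes, and Tubb1 (3.81) the megakaryocyte genes. These values were weak: of 359158 H3K9me1 peaks, 8085 had a q value of at most 0.001, and with these peaks alone the share of genes was 3.04%.

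The marks were set against each other along the genome. Of the length of H3K27ac peaks, 76.7% lay within H3K4me1 peaks, against 6.98% after random shifts of the peaks along their chromosomes, and 0.240% within H3K27me3, against 7.22%. The covered lengths were 54.6 Mb, 168 Mb and 170 Mb. Of the length of H3K9me1 peaks (198.5 Mb), 26.1% lay within H3K4me1, against 7.01%. Genes with both H3K27ac and H3K27me3 within 1 kb of an end, not always the same end, numbered 502, against 1625 if the marks were independent.

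The most extended H3K4me1 regions included the alpha globin cluster and Zfpm1, and those of H3K27me3 the HoxB cluster and Hes1. After joining peaks within 1 kb, the longest H3K4me1 region, of 90341 bp, covered the alpha globin cluster (chromosome 11, 32235118 to 32325458, with Nprl3, Hba-x, Hba-a1 and Hba-a2). Regions over Gse1 (78546 bp), over Zfpm1 (67877 bp), near Gas8 (62843 bp) and over Hipk2 (53358 bp) followed. For H3K27me3 the longest, of 673283 bp, spanned the HoxB cluster (chromosome 11, 96090081 to 96763363). The next were over Tanc2 (485044 bp), a stretch whose nearest gene was Atp5g3 (447104 bp), over Cntn2, Nfasc and Lrrn2 (431132 bp) and around Hes1 (398539 bp). The highest H3K27ac folds were near Pecr (289), at Atp6v0c (265), in Tex14 (254), at Hnrnpa0 (251) and near Wapl (247). H3K9me1 regions were shorter, from 33172 to 49930 bp, the longest near Mxi1 and the next at Selenbp2 and near Fam53a and Rhbg and at Ano7.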

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

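All tests in this part were chosen after the patterns had been seen. HA ChIP in fusion cells gave 164 peaks on chromosome M and unplaced contigs, which the comparisons above leave out, while control HA and IgG ChIP gave 0 there. What drew attention was this difference in called peaks. The fusion HA list was called without an input and the control HA and IgG lists with one, so signal levels were not compared. At 64 of these peaks an H3K27ac summit lay within 1 kb, and the input-based background of the H3K27ac list was over 3 times its floor at 100% of them (interval 94.3 to 100%). Among the 369 HA sites with such a summit outside the 20 of highest fold, the share was 27.1%. For these 64 peaks this is consistent with repeated sequence called without an input, at H3K27ac summits where inputs hold excess reads too. The other 100 peaks stay open, and no biological explanation was tested.

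The 20 HA sites of highest fold are another pattern, with a median of 404 reads at the summit against 28 for all HA sites. Fewer reads in the control HA library, which would leave such sites uncalled there, are argued against by the floors, whose ratio was 0.928. Repeated sequence called without an input is a candidate explanation for Mamdc2, Oasl1, Fam107a and Litaf. Of the 5 sites with an H3K27ac summit within 1 kb, these 4, or 80.0% (interval 37.6 to 96.4%), had an input-based background over 3 times the floor. Of the 369 other HA sites with such a summit, 27.1% did. At Eef1a1 that background was 1.23 times the floor. The other 15 sites had no such value and stay open.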

How the results depend on the processing

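Of 65 alternative values for the main results, 43 stayed within the interval of the main value (within 1.5 times for counts), and none reversed; "low background" below was added after the data were seen. The number of HA sites ranged from 783 (low background) to 1293 (no removal), and erythroid genes with an HA site from 14 to 17. The weakest HA summit held 13 reads, so weaker sites were out of reach at this depth. A q limit of 0.01 removed no fusion HA peak. The values under that limit, counted among the unchanged ones here and for the single lists, thus repeat the main values and say nothing on stability. Values that moved follow. With low background only, fusion HA peaks overlapped control HA at 14.9% and IgG at 9.10%, HA sites overlapped H3K9me1 at 14.7%, and the ratio of H3K27ac folds was 8.98. Within 3 kb of a gene end were 15.5% of HA sites. With 50% of the HA site covered, 28.3% were in H3K27ac. Without removal of background peaks 7.12% were in H3K27me3, close to the random mean, so the deficit there rests on that removal. With mark peaks of q at most 0.001, HA sites were in H3K27me3 at 3.13% and in H3K9me1 at 11.5%; gene ends with H3K4me1 were 55.8%, with H3K27me3 10.2% and with H3K9me1 3.04%; H3K27ac length was within H3K4me1 at 75.1% and within H3K27me3 at 0.178%, and H3K9me1 length within H3K4me1 at 36.1%. Counting peaks in place of length gave 87.9%, 0.602% and 29.3%. With peaks over the gene end itself the shares were 38.2% for H3K27ac, 24.1% for H3K4me1, 9.73% for H3K27me3 and 18.7% for H3K9me1. Narrower windows and stricter limits lower such shares by construction; for the others the cause was not tested. Among the single lists 4 of 60 values moved, each by 1 gene. Motif alternatives were not run, for want of a genome here. No paired analysis was possible because each group holds 1 library, which also rules out leaving out replicates.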

Other observations

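All tests in this part were chosen after the patterns had been seen. Slc4a1 was 1 of 2 erythroid list genes with H3K27me3 at a gene end, and the only one of these with an HA site. Its HA site, at chromosome 11, 102363693 to 102363912, lay between an H3K27me3 peak that ended at 102362942 and another that began at 102364732, in an H3K4me1 peak of fold 9.41. No H3K27ac peak was within 1 kb of a gene end. The genotype behind the H3K27me3 list is open, so it was not shown that these marks lie in the same cells.

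Eef1a1, the gene of a translation elongation factor, had 2 HA sites with 1336 and 1021 reads, 320 and 303 bp wide, at chromosome 9, 78480833 to 78481152 and 78481522 to 78481824. Neither control HA nor IgG had a peak there. The HA background at both was 42.5 reads, 16.3 times the floor, and includes the reads of these 2 peaks. The H3K27ac peak over both (78480115 to 78482585) had 354 reads over a background of 3.84, which is 1.23 times the floor.

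HA sites gathered near the starts of several chromosome assemblies. The nearest gene was Alkbh8 for 34 sites (chromosome 9, 3000559 to 3364644), Sfi1 for 29 (chromosome 11) and Scaf8 for 14 (chromosome 17), and 33, 28 and 14 of these had a background over 3 times the floor in the HA list, which counts the sites' own reads, or in the H3K27ac list. Another 45 sites were on chromosome Y.

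Cd44 had the only control HA peak at an erythroid list gene. At chromosome 2, 102829291 to 102829533, fusion HA ChIP had 223 reads over a background of 6.42 (fold 30.2), and control HA ChIP 159 reads over 22.8 (fold 6.72). Only the control HA background came from an input, so these folds are not like for like.

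Strong acetylation alone is argued against as the cause of HA sites at 15 erythroid genes, with 0.220% of random lists matched on gene length and acetylated length as high, but this rests on the red cell membrane genes. Taken singly, 0.1% of matched lists held as many as the 8 membrane genes, while 8.3% held as many as the 5 transcription factor genes and 53.9% as many as the 2 haem and iron genes, where acetylation alone stays open. High local background in the HA or H3K27ac list is argued against. With sites of low local background only, 14 genes were left, and 0.660% of matched lists held as many. The filter cannot decide on repeated sequence as such, which stays open. Repeats with few reads pass it, and the HA background does not come from an input. The sites at Slc4a1 and Xpo7 lie outside H3K27ac peaks, where the filter has no input-based value. Background of the HA antibody stays open: 1 erythroid gene had a control HA peak, and random draws of as many fusion HA peaks, 256, gave a mean of 3.13 genes (range 0 to 7), of which 15.2% were as low. With that open, no biological explanation is put forward.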
